A study of Homo sapiens with 38 samples.

How the data were processed

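The series holds RNA sequencing of 38 libraries from 5 breast cancer cell lines, and 1 deposited table of gene-level counts was used in full. The series text speaks of more lines and ligands than the labels show, and only what the labels show was used. Per the labels, cells were kept in hormone-free medium for at least 3 days and given a ligand for 24 h. The extraction protocol names 2 library kits, 1 that selects polyadenylated RNA and 1 for total RNA, without saying which sample had which. It also names GNE-274 where the sample labels have G-03046274; the label name is used, and the names are taken for 1 compound only by elimination. Reads were single-end with a length of 50 bases, per the labels, and the build was GRCh 38. The aligner, the counting program, their versions and the strand setting are not given in the sources used here. The deposited values are raw counts per Entrez gene, and the authors applied no normalization to them: all were whole numbers. Gene symbols and positions came from the deposited table, with 29 symbols restored by Entrez identifier from the reference annotation.

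Groups were taken from the labels as cell line and ligand, with 2 libraries in each of 19 groups. Replicate numbers follow the order of deposit and pair nothing. Library totals ran from 22614608 to 39437349 counts, so counting error is small for genes above about 5 CPM; floors cover counting error only, and reads carry no molecular identifiers. Of 30727 genes in the table, 18405 passed filterByExpr by group and were tested.

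The analysis used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. A single edgeR quasi-likelihood model (estimateDisp, glmQLFit with robust estimation, glmQLFTest) with TMM factors and 1 mean per group was fitted to all 38 libraries, which left 19 residual degrees of freedom. The common coefficient of variation between duplicates was 5.25%. TMM factors ran from 0.911 to 1.09. P values were adjusted by Benjamini-Hochberg within each comparison, and a gene was called at an adjusted p below 0.05. Standard errors are the absolute log2 fold change over the square root of F. Tests covered each ligand against DMSO in each line, GDC-0927 against G-03046274 in each line, the pairs of the ligands in MDA-MB-134-VI, averages over the 5 lines, and, for GDC-0927 and G-03046274, whether the effect differed between lines. Comparisons with DMSO in 1 line share the same control libraries, so ligands were compared by direct tests.

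The comparisons, the tests, the alternatives, the rule for named genes and 28 gene lists were chosen before the data were examined. The rule took ESR1, PGR, GREB1, TFF1, PDZK1, CXCL12, MYC, CCND1, AREG and IGFBP4 in every comparison with DMSO. It took the 5 largest rises and falls among called genes changed in the same direction in all 5 lines for each average, and the 5 largest (3 outside MDA-MB-134-VI) among called genes whose duplicates did not overlap for each comparison in 1 line. Both parts asked for at least 5 CPM in the higher group and skipped genes with only a locus or clone name and pseudogenes. It also allowed up to 4 called members per list with the smallest p. Some genes that the rule took, mainly ones whose call ended when 1 library was left out, stand only in the counts of the part on processing. RN7SK, RPPH1 and RMRP levels per library were looked at after their values were seen.

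Lists were tested against all other genes with camera in limma at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of each comparison. The lists printed are estrogen-induced and estrogen-repressed genes, G1/S and DNA replication, mitosis, MYC and ribosome biogenesis, cholesterol synthesis, fatty acid synthesis, ER-stress chaperones, p53 targets, immediate-early genes, BCL2-family genes, NRF2 targets, mitochondrially encoded transcripts, and non-polyadenylated RNAs. Lists of interferon response genes, lysosome genes and endothelial markers are printed in a few comparisons only. A second p is printed where the estimated correlation changed a camera call. For genes whose group had 0 counts, folds are given against a floor of 3 counts over the group, or not at all. A signature of 522 raised and 547 lowered genes was taken from E2 against fulvestrant at an adjusted p below 0.05 and an absolute log2 fold change of at least 1.

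The alternatives were DESeq2 with its own size factors, limma-voom, RLE size factors in edgeR, no filter on low counts, only the libraries of the line compared, an additive model of line and ligand for the averages, each of the 38 libraries left out in turn, and other signatures. For the gene lists and signatures, leaving out T-47D G-03046274 replicate 2 was added after seeing the data, as was a signature without non-polyadenylated RNAs. The method was tested on simulated data, negative binomial counts drawn from the DMSO means and the fitted dispersions with 200 genes changed: at folds of 1.3, 1.5, 2 and 4 it recovered 62%, 90%, 100% and 100% of the changed genes for G-03046274 against DMSO in MDA-MB-134-VI, with 9 false calls, and called 0 genes in an unchanged comparison. For a difference between lines it recovered 40% at a fold of 1.3 and 78% at 1.5. The changed genes were drawn from those above 2 CPM in DMSO of every line. Genes varied independently, with 1 dispersion per gene in all groups. The rates therefore do not cover lower genes or differences between duplicates that many genes share.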

Results

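RNA sequencing measured gene expression in 5 human breast cancer cell lines, T-47D, EFM-19, BT-474, MDA-MB-330 and MDA-MB-134-VI. They had been given an estrogen receptor ligand or DMSO, the solvent, for 24 h. The cells had been kept without hormone before the ligands were added. DMSO, GDC-0927 and G-03046274 were given to all 5 lines, and E2, 4-OH tamoxifen, fulvestrant and GDC-0810 to MDA-MB-134-VI. The labels give 1 nM for E2 and 1 uM for every other ligand. E2 is estradiol, the natural estrogen, and 4-OH tamoxifen is the active metabolite of tamoxifen. Fulvestrant is an antagonist that lowers the amount of the receptor, and the others are estrogen receptor ligands known by their codes. Each of the 19 groups held 2 libraries, so n = 2 per group throughout, and the 38 libraries held 22614608 to 39437349 counts each. Duplicates had a correlation of log CPM across genes of 0.993 to 0.997, and different lines at most 0.883. Values are log2 fold changes ± standard error from edgeR for 18405 genes, and levels are in CPM, counts scaled to the library total and its TMM factor. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. In parentheses after the called numbers of a gene list stand the numbers higher and lower when p was adjusted over the list alone (marked alone), the median log2 fold change and the adjusted p of camera in limma. A second p, from camera with an estimated correlation, is given where it changed the call. Nothing in the labels says whether duplicates were separate cultures, so the tests measure only the spread between these libraries.

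The 10 genes given in every comparison with DMSO follow with their position on GRCh 38. Estrogen receptor alpha is encoded by ESR1 (Entrez 2099) at 151690496 to 152103274 on chromosome 6, and the progesterone receptor by PGR (Entrez 5241) at 101029624 to 101129813 on chromosome 11. An estrogen-induced coactivator is GREB1 (Entrez 9687) at 11534116 to 11642788 on chromosome 2, and a secreted trefoil protein TFF1 (Entrez 7031) at 42362282 to 42366535 on chromosome 21. A scaffold protein is encoded by PDZK1 (Entrez 5174) at 145670852 to 145707404 on chromosome 1, and a chemokine by CXCL12 (Entrez 6387) at 44370153 to 44385097 on chromosome 10. A transcription factor is MYC (Entrez 4609) at 127736069 to 127741434 on chromosome 8, and cyclin D1 CCND1 (Entrez 595) at 69641105 to 69654474 on chromosome 11. A ligand of the EGF receptor is encoded by AREG (Entrez 374) at 74445098 to 74455009 on chromosome 4, and a protein that binds insulin-like growth factors by IGFBP4 (Entrez 3487) at 40443424 to 40457730 on chromosome 17. PGR, TFF1 and IGFBP4 overlap annotated loci on the opposite strand by 737, 8 and 736 bases, and the strand of the counts is not given in the sources used here. In DMSO, ESR1 stood between 182 CPM in EFM-19 and 427 CPM in MDA-MB-330.

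E2 against DMSO in MDA-MB-134-VI showed the response of this line to estrogen, and estrogen-induced genes rose together while estrogen-repressed genes fell. PDZK1 rose by 3.15 ± 0.11 (36.0 against 4.04 CPM), GREB1 by 2.05 ± 0.09, TFF1 by 1.91 ± 0.07, AREG by 1.86 ± 0.09 and IGFBP4 by 1.78 ± 0.05. PGR rose by 1.93 ± 0.28 from a low level (1.18 against 0.313 CPM), MYC by 0.80 ± 0.06, CCND1 by 0.48 ± 0.07 and ESR1 by 0.41 ± 0.05. The largest rises were in PGLYRP2, an amidase that cleaves peptidoglycan (4.59 ± 0.12), KIAA0125 (4.08 ± 0.27), the Fc receptor-like gene FCRLB (3.60 ± 0.10), the potassium channel gene KCNQ5 (3.47 ± 0.21) and SH2D3C (3.34 ± 0.27). The largest falls were in C10orf10 (-5.70 ± 0.14), the beta-defensin gene DEFB132 (-2.79 ± 0.20), the ubiquitin ligase gene FBXO32 (-2.79 ± 0.10), FBN2 (-2.78 ± 0.23) and the microtubule gene MAP1B (-2.77 ± 0.11). Of the 50 estrogen-induced genes 44 rose and 2 fell (46 and 2 alone, median 1.14, adjusted p = 3.08e-58). Of 18 estrogen-repressed genes 16 fell (0 and 18 alone, median -0.93, adjusted p = 1.24e-22), among them IL1R1 (-1.75 ± 0.05) and TXNIP (-1.57 ± 0.04). Genes of G1/S and DNA replication rose in 31 of 32 cases (32 and 0 alone, median 0.60, adjusted p = 2.11e-27). CDC6 was at 0.99 ± 0.06, E2F1 at 0.90 ± 0.06 and MCM6 at 0.62 ± 0.05. Of 30 mitosis genes 16 rose (18 and 0 alone, median 0.20, adjusted p = 1.95e-04, or 0.116 with an estimated correlation).

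Genes of MYC and ribosome biogenesis rose with E2 in 18 of 22 cases (20 and 0 alone, median 0.35, adjusted p = 5.31e-09), including NOP56 (0.47 ± 0.04) and BOP1 (0.80 ± 0.08). Cholesterol synthesis genes rose in 17 of 24 cases and fell in 1 (17 and 1 alone, median 0.32, adjusted p = 3.36e-08). HMGCS1 was at 0.57 ± 0.05 and DHCR7 at 0.70 ± 0.06. Of 12 fatty acid synthesis genes 8 rose and 1 fell (8 and 2 alone, median 0.26, adjusted p = 3.78e-05), with SCD, which desaturates fatty acids, at 1.00 ± 0.04. Among 14 ER-stress chaperones 11 rose and 2 fell (11 and 2 alone, median 0.47, adjusted p = 9.19e-07). HSPA5 was at 0.62 ± 0.04. Among 14 p53 targets 1 rose and 7 fell (1 and 7 alone, median -0.31, adjusted p = 9.80e-06). BTG2 was at -1.30 ± 0.07 and CDKN1A at -0.66 ± 0.05, and among 13 BCL2-family genes 2 rose and 6 fell (2 and 6 alone, median -0.22, adjusted p = 0.0242). the pro-apoptotic genes BBC3 was at -1.31 ± 0.12 and BIK at -1.26 ± 0.10. Immediate-early genes rose in 2 and fell in 10 of 18 cases (2 and 11 alone, median -0.42, adjusted p = 0.00128, or 0.0846 with an estimated correlation). In all, edgeR called 2927 genes higher and 3171 lower, 735 of them by at least 2-fold. CXCL12 fell by 0.25 ± 0.07, a call that ended without DMSO replicate 2 (-0.16, adjusted p = 0.173), and E2 replicate 1 held 65.9 CPM of the small nuclear RNA RN7SK against 1.70 in its duplicate.

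**Figure D1:**
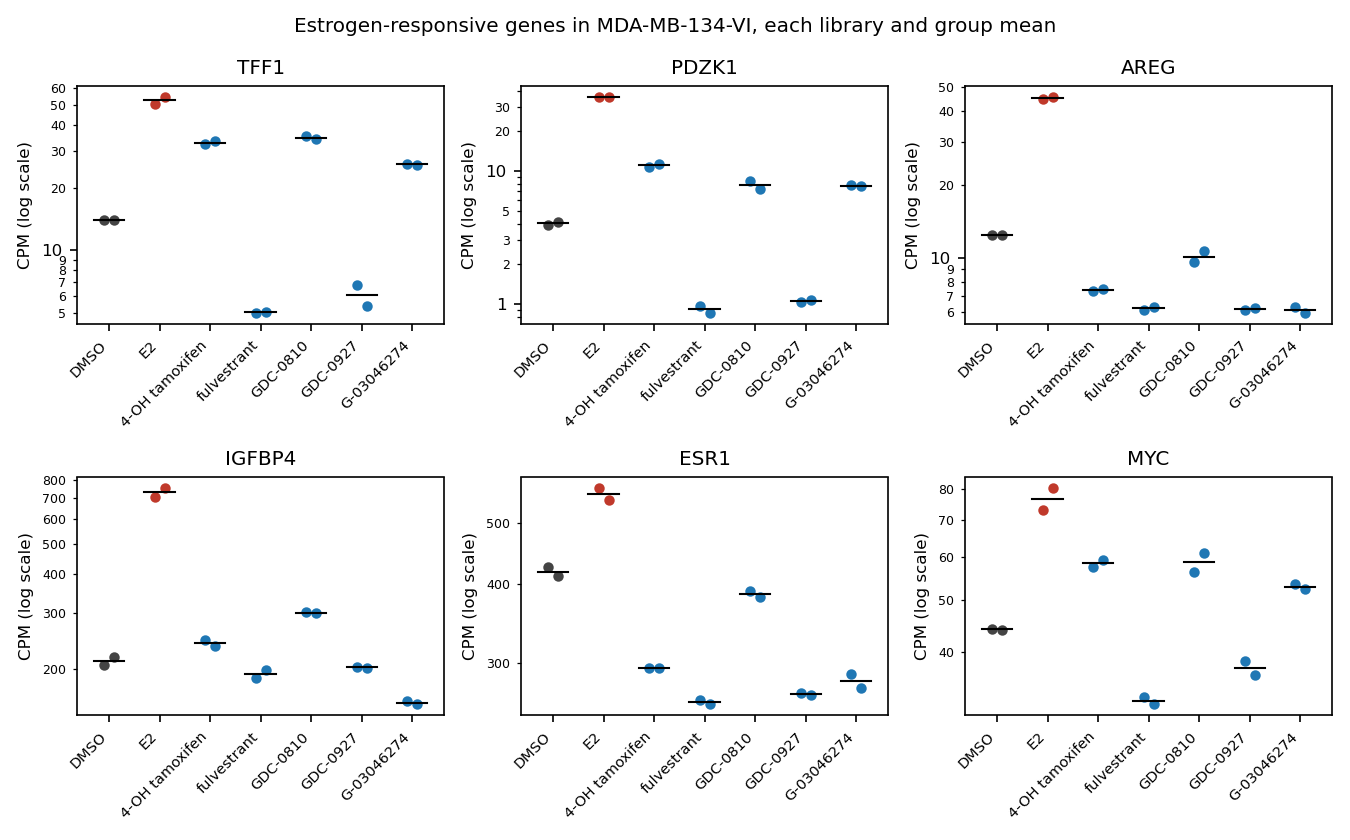
Level in CPM (log axis) of 6 genes in each MDA-MB-134-VI library by ligand; points are the 2 libraries of a group and lines their mean. PDZK1 stood at a mean of 36.0 CPM with E2, 4.04 with DMSO, 0.908 with fulvestrant and 1.05 with GDC-0927.

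4-OH tamoxifen against DMSO asked what this ligand did without estrogen, and part of the estrogen-induced genes rose with it, together with genes of sterol and fatty acid synthesis. FCRLB rose by 4.90 ± 0.10 (115 against 3.86 CPM), PGLYRP2 by 4.37 ± 0.12, the prostaglandin E synthase gene PTGES by 2.72 ± 0.08, the ion channel gene ASIC2 by 1.85 ± 0.13 and SCD by 1.61 ± 0.04 (903 against 296 CPM). PDZK1 rose by 1.44 ± 0.11, TFF1 by 1.23 ± 0.07 and MYC by 0.40 ± 0.06, whereas AREG fell by 0.75 ± 0.11 and ESR1 by 0.51 ± 0.05. PGR (0.34 ± 0.37), GREB1 (-0.05 ± 0.09), CXCL12 (-0.13 ± 0.07) and CCND1 (0.03 ± 0.07) were not called. The largest falls were in IGFBP5 (-1.31 ± 0.21), FBN2 (-0.97 ± 0.18), C10orf10 (-0.88 ± 0.08), RASL11A (-0.86 ± 0.12) and DCX (-0.76 ± 0.08). Of the estrogen-induced genes 22 of 50 rose and 3 fell (24 and 6 alone, median 0.17, adjusted p = 2.35e-24). Of 18 estrogen-repressed genes 5 fell (0 and 10 alone, median -0.19, adjusted p = 1.44e-06). Cholesterol synthesis genes rose in 18 of 24 cases (18 and 0 alone, median 0.38, adjusted p = 3.30e-46). INSIG1 was at 0.84 ± 0.05 and HMGCS1 at 0.78 ± 0.05. Fatty acid synthesis genes rose in 9 of 12 (12 and 0 alone, median 0.37, adjusted p = 2.06e-33). THRSP was at 1.39 ± 0.13. Of 32 G1/S and DNA replication genes 12 rose (22 and 0 alone, median 0.19, adjusted p = 2.50e-18). RRM2 was at 0.40 ± 0.06 and CDC6 at 0.35 ± 0.06. The test called 420 genes higher and 323 lower. Leaving out any 1 of the 4 libraries gave 272 to 433 genes in all, leaving out either T-47D G-03046274 library 1192, and the libraries of this line alone 1478. IGFBP4 rose by 0.19 ± 0.05, a call that ended without DMSO replicate 1 (adjusted p = 0.192) or 4-OH tamoxifen replicate 1 (adjusted p = 0.165), and the calls of FBN2 without 4-OH tamoxifen replicate 1 (adjusted p = 0.0512) and of IGFBP5 with limma-voom (adjusted p = 0.0799) ended too.

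Fulvestrant against DMSO asked whether blocking the receptor lowered what remained of estrogen-induced expression, and part of the estrogen-induced genes fell. PDZK1 fell by 2.15 ± 0.17 (0.908 against 4.04 CPM), TFF1 by 1.47 ± 0.09 and the secreted glycoprotein gene STC2 by 1.40 ± 0.07. The matrix protein gene MGP was at -2.07 ± 0.14. SUSD3 fell by 1.09 ± 0.09, SERPINA5 by 1.09 ± 0.09 and AREG by 1.00 ± 0.11. ESR1 fell by 0.69 ± 0.05 and MYC by 0.44 ± 0.06, and C10orf10 rose by 0.47 ± 0.07. PGR (-1.46 ± 0.49), GREB1 (-0.24 ± 0.09), CXCL12 (0.14 ± 0.07) and IGFBP4 (-0.14 ± 0.05) were not called. Of the estrogen-induced genes 17 of 50 fell (0 and 27 alone, median -0.23, adjusted p = 2.03e-35). Of 18 estrogen-repressed genes 4 rose (7 and 0 alone, median 0.16, adjusted p = 1.89e-13). Of 32 G1/S and DNA replication genes 20 fell (0 and 28 alone, median -0.29, adjusted p = 8.20e-47). E2F1 was at -0.50 ± 0.06 and RRM2 at -0.47 ± 0.06. Cholesterol synthesis genes fell in 6 of 24 cases (0 and 8 alone, median -0.12, adjusted p = 2.23e-09) and fatty acid synthesis genes in 3 of 12 (0 and 3 alone, median -0.11, adjusted p = 2.80e-05). SCD was at -0.33 ± 0.04. The test called 61 genes higher and 231 lower. Leaving out any 1 of the 4 libraries gave 96 to 148 genes in all, leaving out either T-47D G-03046274 library 448, and the libraries of this line alone 567. CCND1 (-0.25 ± 0.07) and 4 of the largest rises, DLX2 (0.65 ± 0.17), MIR4800 (0.54 ± 0.12), TM6SF1 (0.53 ± 0.14) and EDN2 (0.48 ± 0.12), lost their call whichever of the 4 libraries was left out.

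GDC-0810 against DMSO gave the response to another ligand at the same dose, and part of the estrogen-induced genes and most G1/S and DNA replication genes rose. FCRLB rose by 1.96 ± 0.11, TFF1 by 1.31 ± 0.07 (34.6 against 14.0 CPM), PTGES by 1.14 ± 0.08, PDZK1 by 0.94 ± 0.12, MAMLD1 by 0.81 ± 0.09, IGFBP4 by 0.51 ± 0.05 and MYC by 0.41 ± 0.06. C10orf10 fell by 1.12 ± 0.08. ESR1 (-0.12 ± 0.05), PGR (-1.53 ± 0.49), GREB1 (0.30 ± 0.09), CCND1 (0.08 ± 0.07) and AREG (-0.29 ± 0.10) were not called. Of the estrogen-induced genes 13 of 50 rose and 1 fell (23 and 5 alone, median 0.17, adjusted p = 8.06e-20). Of 18 estrogen-repressed genes 6 fell (1 and 10 alone, median -0.20, adjusted p = 8.44e-12). Of 32 G1/S and DNA replication genes 25 rose (29 and 0 alone, median 0.33, adjusted p = 1.83e-63). RRM2 was at 0.48 ± 0.06, CDC6 at 0.47 ± 0.06 and E2F1 at 0.43 ± 0.06. Of 24 cholesterol synthesis genes 2 rose (5 and 0 alone, median 0.08, adjusted p = 9.40e-06, or 0.0625 with an estimated correlation). The test called 201 genes higher and 127 lower. Leaving out any 1 of the 4 libraries gave 109 to 155 genes in all, leaving out a T-47D G-03046274 library 578 or 579, and the libraries of this line alone 688. Smaller falls depended on single libraries or the tool: CXCL12 (-0.39 ± 0.07; without DMSO replicate 2 adjusted p = 0.111), IGFBP5 (-1.07 ± 0.20; 0.0506 without that library and 0.181 with limma-voom) and MGP (-0.67 ± 0.12; 0.0796 with limma-voom).

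GDC-0927 against DMSO in MDA-MB-134-VI lowered G1/S and DNA replication genes and part of the estrogen-induced genes. MGP fell by 2.01 ± 0.14, PDZK1 by 1.94 ± 0.16 (1.05 against 4.04 CPM), GP2 by 1.25 ± 0.14, TFF1 by 1.18 ± 0.09, STC2 by 1.11 ± 0.07, AREG by 1.01 ± 0.11 and ESR1 by 0.64 ± 0.05. SCD rose by 0.58 ± 0.04; the smaller rises of MIR4800 (0.53 ± 0.13) and KLF9 (0.40 ± 0.09) lost their call whichever of the 4 libraries was left out. PGR (-1.14 ± 0.48), GREB1 (-0.24 ± 0.09), CXCL12 (0.05 ± 0.07), MYC (-0.23 ± 0.06), CCND1 (-0.15 ± 0.07) and IGFBP4 (-0.07 ± 0.05) were not called. Of the estrogen-induced genes 10 of 50 fell (0 and 17 alone, median -0.17, adjusted p = 9.56e-28). Of 18 estrogen-repressed genes 3 rose (5 and 0 alone, median 0.11, adjusted p = 8.97e-10). Of 32 G1/S and DNA replication genes 20 fell (0 and 31 alone, median -0.35, adjusted p = 8.88e-67). TK1 was at -0.57 ± 0.07 and E2F1 at -0.53 ± 0.06. The list of mitosis genes (median -0.09, adjusted p = 8.62e-06, or 0.0728 with an estimated correlation) and that of non-polyadenylated RNAs, fixed as a sign of the library kit (median -0.65, adjusted p = 0.0236, or 0.457), lost their call with an estimated correlation. Of 24 cholesterol synthesis genes 2 rose (4 and 0 alone, median 0.04, adjusted p = 6.60e-04, or 0.197 with an estimated correlation). The test called 24 genes higher and 155 lower, and leaving out any 1 of the 4 libraries gave 76 to 89 genes in all and the libraries of this line alone 317.

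G-03046274 against DMSO in MDA-MB-134-VI moved estrogen-induced genes in both directions and raised genes of sterol and fatty acid synthesis. FCRLB rose by 4.09 ± 0.10, PGLYRP2 by 3.74 ± 0.12, PTGES by 2.03 ± 0.08, GP2 by 1.32 ± 0.12, PDZK1 by 0.93 ± 0.12 and TFF1 by 0.89 ± 0.07. AREG fell by 1.02 ± 0.11, ESR1 by 0.58 ± 0.05, GREB1 by 0.50 ± 0.09 and IGFBP4 by 0.44 ± 0.05. MAP6 (-1.03 ± 0.17), DCX (-0.89 ± 0.08) and MS4A15 (-0.87 ± 0.12) were also among the largest falls, and PGR (0.62 ± 0.34) and CCND1 (-0.04 ± 0.07) were not called. Of the estrogen-induced genes 17 of 50 rose and 8 fell (18 and 11 alone, median 0.01, adjusted p = 0.00401). Of 18 estrogen-repressed genes 3 fell (0 and 3 alone, median -0.10, adjusted p = 0.0127). Cholesterol synthesis genes rose in 10 of 24 cases and fell in 1 (15 and 1 alone, median 0.18, adjusted p = 5.66e-14). INSIG1 was at 0.51 ± 0.05. Fatty acid synthesis genes rose in 4 of 12 (4 and 0 alone, median 0.09, adjusted p = 9.31e-11). SCD was at 0.84 ± 0.04 and THRSP at 1.21 ± 0.13. G1/S and DNA replication genes rose in 3 of 32 cases (4 and 0 alone, median 0.04, adjusted p = 0.00401, or 0.128 with an estimated correlation). The nuclear RNA MALAT1 rose by 1.62 ± 0.28, with 139 and 197 CPM against 58.7 and 50.5, beside 1 of 18 non-polyadenylated RNAs that rose (1 and 0 alone, median 0.45, adjusted p = 0.00556, or 0.278 with an estimated correlation). The test called 275 genes higher and 426 lower. Leaving out any 1 of the 4 libraries gave 206 to 319 genes in all, leaving out a T-47D G-03046274 library 1227 or 1229, and the libraries of this line alone 1788. CXCL12 (-0.29 ± 0.07) lost its call without DMSO replicate 2 (adjusted p = 0.366), G-03046274 replicate 1 (0.136) or replicate 2 (0.15), MYC (0.26 ± 0.06) without DMSO replicate 1 (0.0511), DMSO replicate 2 (0.0713) or G-03046274 replicate 1 (0.0683), and IGFBP5 (-1.28 ± 0.20) with limma-voom (0.0615).

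Direct tests between ligands in MDA-MB-134-VI asked where they differed at 1 uM, and the largest differences lay between 4-OH tamoxifen, GDC-0810 or G-03046274 on one side and fulvestrant or GDC-0927 on the other. Against fulvestrant, 4-OH tamoxifen gave higher FCRLB (5.24 ± 0.11), PGLYRP2 (4.71 ± 0.13), PDZK1 (3.59 ± 0.15) and TFF1 (2.70 ± 0.08) and lower C10orf10 (-1.35 ± 0.08) and MAP1B (-1.08 ± 0.09), with 30 of 50 estrogen-induced genes higher and 3 lower (32 and 4 alone, median 0.48, adjusted p = 1.47e-40). Against GDC-0927 it gave higher FCRLB (5.46 ± 0.11), PDZK1 (3.38 ± 0.15) and GP2 (2.62 ± 0.13). Fulvestrant gave lower PDZK1 (-3.10 ± 0.15), TFF1 (-2.78 ± 0.08) and AMZ1 (-2.63 ± 0.20) than GDC-0810, with 30 of 32 G1/S and DNA replication genes lower (0 and 32 alone, median -0.61, adjusted p = 3.36e-72). Relative to G-03046274, fulvestrant gave lower FCRLB (-4.43 ± 0.11), PGLYRP2 (-4.09 ± 0.13) and PDZK1 (-3.08 ± 0.15) and higher C10orf10 (1.14 ± 0.08), and non-polyadenylated RNAs were lower in 2 of 18 cases (0 and 4 alone, median -0.823, adjusted p = 0.0147, or 0.388 with an estimated correlation). GDC-0810 gave higher PDZK1 (2.88 ± 0.15) and TFF1 (2.49 ± 0.08) than GDC-0927, with 32 of 32 G1/S and DNA replication genes higher (32 and 0 alone, median 0.67, adjusted p = 1.45e-90). 4-OH tamoxifen and fulvestrant differed in 2554 genes, 4-OH tamoxifen and GDC-0927 in 1445, fulvestrant and GDC-0810 in 2050, fulvestrant and G-03046274 in 2396, and GDC-0810 and GDC-0927 in 1477. With the libraries of this line alone these were 3872, 2337, 3088, 3958 and 2347. Without single libraries these became 1589 and 1343 (4-OH tamoxifen replicates 1 and 2) or 1135 (fulvestrant replicate 2), 890 and 802 (4-OH tamoxifen replicates 1 and 2) or 722 (GDC-0927 replicate 2), 1111 to 1297 (any 1 of the 4), 972 (fulvestrant replicate 2) or 1304 and 1081 (G-03046274 replicates 1 and 2), and 759 to 875 (any 1 of the 4).

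E2 against fulvestrant, which had the most called genes of the contrasts tested in this line, called 7338 genes, with KCNQ5 at 5.51 ± 0.27, PDZK1 at 5.30 ± 0.14 and MGP at 4.64 ± 0.12 and, in the other direction, C10orf10 at -6.17 ± 0.13, DLX2 at -3.38 ± 0.26 and NPPC at -3.21 ± 0.27. E2 against GDC-0810 called 4301 genes, with PGLYRP2 at 3.85 ± 0.11, MGP at 3.23 ± 0.10 and C10orf10 at -4.58 ± 0.15. The 522 genes raised and 547 lowered by at least 2-fold with E2 against fulvestrant served as a signature, chosen on libraries of this series and tested only in contrasts that share none of them. It held 21 raised and 2 lowered non-polyadenylated RNAs by name, such as RN7SK, RMRP and RPPH1, which stood high in E2 replicate 1 and not in its duplicate. Of the raised genes 128 rose and 16 fell with 4-OH tamoxifen (median 0.20, camera adjusted p = 5.72e-27), 97 rose and 3 fell with GDC-0810 (median 0.23, adjusted p = 5.42e-32), 83 rose and 24 fell with G-03046274 (median 0.12, adjusted p = 3.60e-10), and 1 rose and 94 fell with GDC-0927 (median -0.28, adjusted p = 1.31e-45). Of the lowered genes 77 fell and 1 rose with 4-OH tamoxifen, 59 fell with GDC-0810, 66 fell with G-03046274, and 9 rose with GDC-0927. Without these RNAs, a test chosen after seeing the data, the numbers for the raised genes stayed the same except for 82 risen with G-03046274.

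Some pairs differed less. Fulvestrant and GDC-0927 differed in 11 genes in edgeR (21 with DESeq2), all lower with fulvestrant, and most belonged to sterol and fatty acid synthesis: SCD (-0.90 ± 0.04) and INSIG1 (-0.53 ± 0.05). The same pathway held HMGCS1 (-0.36 ± 0.05; without fulvestrant replicate 2 adjusted p = 0.16) and IDI1 (-0.39 ± 0.07), whose call ended whichever of the 4 libraries was left out and whose locus overlaps IDI2-AS1 on the other strand by 1009 bases. Cholesterol synthesis genes were lower in 5 of 24 cases (0 and 13 alone, median -0.15, adjusted p = 3.19e-32), fatty acid synthesis genes in 2 of 12 (0 and 5 alone, median -0.20, adjusted p = 3.19e-27) and estrogen-induced genes in 1 of 50 (0 and 4 alone, median -0.05, adjusted p = 8.58e-05). Leaving out fulvestrant replicate 1, fulvestrant replicate 2 or GDC-0927 replicate 1 gave 5, 4 or 5 genes, a T-47D G-03046274 library 20, and the libraries of this line alone 24. The 95% intervals of this difference were -0.137 to 0.05 for ESR1, -0.659 to 0.238 for PDZK1, -0.505 to -0.087 for TFF1 and -1.596 to 0.958 for PGR. 4-OH tamoxifen and G-03046274 differed in 119 genes in edgeR (367 with DESeq2, 189 with limma-voom, 234 with no filter on low counts and 493 with the libraries of this line alone), 108 of them higher with 4-OH tamoxifen: FCRLB (0.81 ± 0.08), SCD (0.77 ± 0.04), PTGES (0.69 ± 0.07), IGFBP4 (0.63 ± 0.05) and HMGCS1 (0.41 ± 0.05), with 12 of 50 estrogen-induced genes (22 and 0 alone, median 0.15, adjusted p = 4.84e-25) and 8 of 24 cholesterol synthesis genes (16 and 0 alone, median 0.20, adjusted p = 7.04e-24) higher. The list of non-polyadenylated RNAs shifted downward beside them (median -0.959, adjusted p = 8.18e-07, or 0.0691 with an estimated correlation). Its intervals were -0.023 to 0.164 for ESR1, 0.294 to 0.728 for PDZK1 and 0.53 to 0.733 for IGFBP4. Leaving out 1 of its 4 libraries gave 15 to 52 genes, and a T-47D G-03046274 library 380. 4-OH tamoxifen and GDC-0810 differed in 214 genes (95 without 4-OH tamoxifen replicate 2, 128 without replicate 1, 96 without GDC-0810 replicate 2, 370 without a T-47D G-03046274 library, 365 with no filter on low counts, 495 with the libraries of this line alone), with PGLYRP2 at 3.63 ± 0.11, SCD at 1.73 ± 0.04, ESR1 at -0.39 ± 0.05 and 12 of 24 cholesterol synthesis genes higher (18 and 0 alone, median 0.28, adjusted p = 1.47e-41). GDC-0810 and G-03046274 differed in 514 genes, with IGFBP4 at 0.95 ± 0.05, GREB1 at 0.80 ± 0.09, PGLYRP2 at -3.01 ± 0.11 and SCD at -0.96 ± 0.04, and non-polyadenylated RNAs shifted downward (median -0.87, adjusted p = 7.00e-05, or 0.103 with an estimated correlation). The libraries of this line alone gave 1408. Any 1 of the 4 libraries left out gave 130 to 217 genes, and a T-47D G-03046274 library 988 or 989.

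GDC-0927 against G-03046274 in MDA-MB-134-VI compared the ligands that all 5 lines received, and part of the estrogen-induced genes and most G1/S genes were lower with GDC-0927. FCRLB (-4.66 ± 0.11), PGLYRP2 (-3.15 ± 0.12), PDZK1 (-2.87 ± 0.15), GP2 (-2.57 ± 0.13) and PTGES (-2.25 ± 0.08) were lower, and MAP6 (1.06 ± 0.17), the dopamine receptor gene DRD1 (0.99 ± 0.18), C10orf10 (0.91 ± 0.08), NRK (0.90 ± 0.14) and FBXO32 (0.84 ± 0.08) were higher. Estrogen-induced genes were lower in 25 and higher in 5 of 50 cases (6 and 27 alone, median -0.22, adjusted p = 2.23e-21), G1/S and DNA replication genes lower in 24 of 32 (0 and 30 alone, median -0.40, adjusted p = 7.95e-46), and estrogen-repressed genes higher in 8 of 18 (12 and 0 alone, median 0.23, adjusted p = 5.15e-11). The mitosis list lost its call with an estimated correlation (median -0.08, adjusted p = 9.62e-04, or 0.167). Of the genes E2 raised against fulvestrant 183 were lower and 5 higher with GDC-0927 (median -0.39). Non-polyadenylated RNAs were lower in 3 of 18 cases (0 and 8 alone, median -1.54, adjusted p = 2.44e-05, or 0.0955 with an estimated correlation). The test called 543 genes higher and 557 lower. Leaving out any 1 of the 4 libraries gave 475 to 606 genes in all, a T-47D G-03046274 library 1666 or 1667, and the libraries of this line alone 2116.

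**Figure D2:**
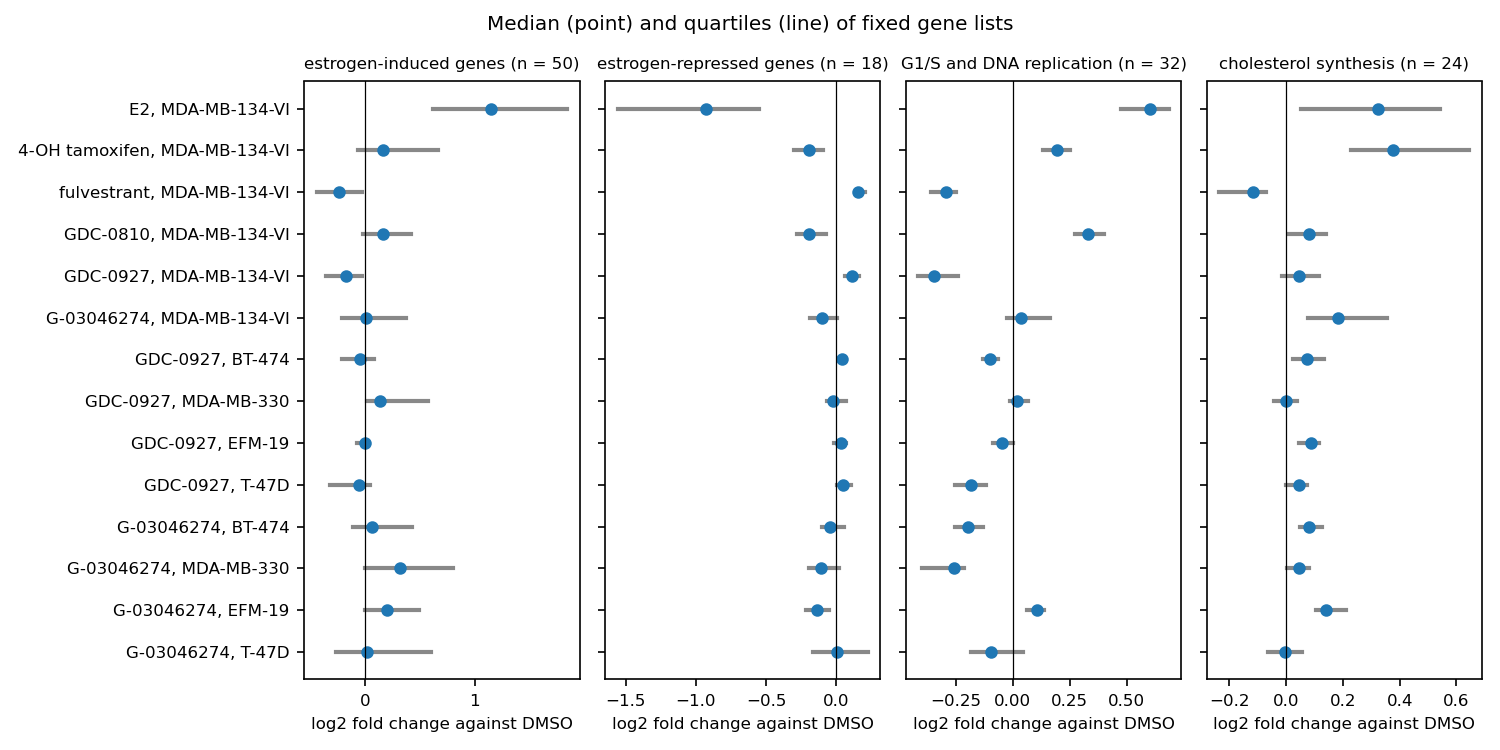
Median and quartiles of the fitted log2 fold changes against DMSO of the genes of 4 lists, by comparison. The G1/S and DNA replication list had its highest median with E2 in MDA-MB-134-VI (0.60) and its lowest with GDC-0927 in the same line (-0.35).

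In BT-474 GDC-0927 lowered 5 of 50 estrogen-induced genes and G-03046274 raised 12. With GDC-0927, TCN1, which binds vitamin B12, fell by 1.87 ± 0.09 (46.5 against 170 CPM), the mitochondrial phosphatase gene PPM1K by 1.44 ± 0.11, FGD3 by 1.37 ± 0.10, SUSD3 by 1.10 ± 0.14, MYC by 0.78 ± 0.07 and STC2 by 0.57 ± 0.07. SCD rose by 0.42 ± 0.04 and IGFBP4 by 0.36 ± 0.05. ESR1 (-0.14 ± 0.05), GREB1 (-0.30 ± 0.10), TFF1 (-0.18 ± 0.06), PDZK1 (1.14 ± 0.63), CXCL12 (-0.19 ± 0.14), CCND1 (0.04 ± 0.07) and AREG (-0.16 ± 0.20) were not called, and PGR fell by 0.37 ± 0.06, a call that ended without DMSO replicate 1 (adjusted p = 0.0975) or GDC-0927 replicate 2 (0.182). Estrogen-induced genes fell in 5 of 50 cases and rose in 1 (5 and 10 alone, median -0.04, adjusted p = 0.00138). With 1 member that had a group at 0 counts placed at its bound the median was -0.024. With G-03046274, KIF12 rose by 1.90 ± 0.16, PTGES by 1.76 ± 0.08, AGR3 by 1.64 ± 0.12, the amino acid transporter gene SLC7A5 by 1.15 ± 0.08 and IGFBP4 by 0.59 ± 0.05, and PPM1K fell by 1.65 ± 0.11 and COLCA1 by 1.37 ± 0.14. Estrogen-induced genes rose in 12 of 50 cases and fell in 5 (13 and 8 alone, median 0.07, adjusted p = 1.60e-05). G1/S and DNA replication genes fell in 7 of 32 cases (0 and 23 alone, median -0.19, adjusted p = 1.85e-18). Mitochondrially encoded transcripts, fixed as a sign of RNA quality, shifted downward beside these changes with none of 15 called (median -0.236, adjusted p = 0.003, or 0.628 with an estimated correlation). With GDC-0927 they did so too (median -0.117, adjusted p = 0.0145, or 0.624). ESR1 (-0.13 ± 0.05), PGR (0.04 ± 0.06), TFF1 (-0.19 ± 0.06), PDZK1 (0.25 ± 0.72), MYC (-0.03 ± 0.07), CCND1 (-0.10 ± 0.07) and AREG (0.05 ± 0.20) were not called. GREB1 (-0.38 ± 0.10), CXCL12 (0.54 ± 0.13) and the ubiquitin ligase gene HERC6 (-1.55 ± 0.33) lost their call whichever of the 4 libraries was left out. Tested directly, GDC-0927 gave lower AGR3 (-1.86 ± 0.12), PTGES (-1.75 ± 0.08) and KIF12 (-1.66 ± 0.16) and higher COLCA1 (1.12 ± 0.14), TMPRSS3 (0.96 ± 0.11) and RPS6KL1 (0.95 ± 0.14), with 14 of 50 estrogen-induced genes lower and 3 higher (5 and 18 alone, median -0.17, adjusted p = 5.66e-14). The counts were 45 genes with GDC-0927 (4 higher), 353 with G-03046274 (214 higher) and 303 for the direct test (93 higher). With any 1 of the 4 libraries left out the tests gave 19 to 25, 150 to 191 and 130 to 156, and a T-47D G-03046274 library 567 or 569 and 455 for the last 2. With the BT-474 libraries alone they gave 141, 1233 and 1159.

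In MDA-MB-330 part of the estrogen-induced genes rose, 8 of 50 with GDC-0927 and 23 with G-03046274. With GDC-0927, IGFBP4 rose by 1.47 ± 0.05 (203 against 73.2 CPM), the annexin gene ANXA9 by 0.95 ± 0.07, the receptor kinase gene RET by 0.86 ± 0.11, TFF1 by 0.61 ± 0.06 and SLC9A3R1 by 0.42 ± 0.05, while the cytokine gene TNFSF15 fell by 0.90 ± 0.09 and PPM1K by 0.87 ± 0.10. Estrogen-induced genes rose in 8 of 50 cases (15 and 2 alone, median 0.14, adjusted p = 1.17e-19), and with 6 members that had a group at 0 counts placed at their bound the median was 0.06. PGR (0.02 ± 0.12), GREB1 (0.25 ± 0.09), PDZK1 (-0.46 ± 0.39), MYC (0.44 ± 0.18), CCND1 (0.12 ± 0.07) and AREG (0.03 ± 0.09) were not called, CXCL12 had 1 count against 0, FGD3 (-0.63 ± 0.10) lost its call without GDC-0927 replicate 2 (adjusted p = 0.121), and ESR1 (-0.20 ± 0.05) whichever of the 4 libraries was left out. With G-03046274, PGLYRP2 rose by 7.20 ± 0.18 (39.0 against 0.256 CPM), PDZK1 by 3.91 ± 0.21, RET by 2.06 ± 0.10, IGFBP4 by 1.56 ± 0.05, SLC9A3R1 by 1.09 ± 0.05, TFF1 by 0.87 ± 0.06 and GREB1 by 0.62 ± 0.09. The keratin gene KRT13 and WFIKKN2 had 369 and 527 counts against 0 in DMSO, which puts them at least 137-fold and 196-fold higher with a floor of 3 counts over the group. RPS6KL1 fell by 1.40 ± 0.14, MAT1A by 1.23 ± 0.16 and ESR1 by 0.29 ± 0.05, whereas CCND1 (-0.01 ± 0.07) and AREG (0.11 ± 0.09) were not called and CXCL12 had 0 counts in both groups. PGR (0.54 ± 0.12) lost its call without DMSO replicate 2 (adjusted p = 0.0934) or G-03046274 replicate 2 (0.0771), HERC6 (-1.52 ± 0.33) without DMSO replicate 1 (-0.55, 0.499) or G-03046274 replicate 2 (0.17), and MYC (0.79 ± 0.17) whichever of the 4 was left out.

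Estrogen-induced genes rose with G-03046274 in MDA-MB-330 in 23 of 50 cases and fell in 2 (26 and 4 alone, median 0.32, adjusted p = 5.12e-44). G1/S and DNA replication genes fell in 18 of 32 cases (0 and 27 alone, median -0.26, adjusted p = 2.02e-30). CDC45 was at -0.63 ± 0.09, MCM10 at -0.58 ± 0.07 and CDC6 at -0.51 ± 0.07. Of 12 NRF2 targets 4 fell (1 and 7 alone, median -0.16, adjusted p = 7.52e-05). NQO1 was at -0.35 ± 0.06. Tested directly, GDC-0927 gave lower PGLYRP2 (-3.85 ± 0.12) and higher RPS6KL1 (1.46 ± 0.14), MAT1A (1.21 ± 0.16) and SLC7A2 (1.07 ± 0.13), with 20 of 50 estrogen-induced genes lower and 4 higher (5 and 21 alone, median -0.21, adjusted p = 2.35e-19) and 20 of 32 G1/S and DNA replication genes higher (27 and 0 alone, median 0.29, adjusted p = 3.53e-34). Mitochondrially encoded transcripts shifted downward in that test (median -0.235, adjusted p = 0.00666, or 0.519 with an estimated correlation) and with GDC-0927 against DMSO (median -0.119, adjusted p = 0.0121, or 0.786). Interferon response genes shifted downward against DMSO with GDC-0927 (median -0.385, adjusted p = 1.01e-04, or 0.786) and with G-03046274 (median -0.431, adjusted p = 0.00128, or 0.427). The counts were 39 genes with GDC-0927 (18 higher; 21 without DMSO replicate 1, 63 with DESeq2 and 89 with no filter on low counts), 597 with G-03046274 (335 higher; 358 without DMSO replicate 1 and 366 without G-03046274 replicate 1) and 614 for the direct test (324 higher; 334 without G-03046274 replicate 1 and 328 without GDC-0927 replicate 2).

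In EFM-19 GDC-0927 changed 1 gene in edgeR, a call that ended whichever of the 4 libraries was left out; 483 genes had an unadjusted p below 0.05, DESeq2 called 9 and limma-voom 4. edgeR called 33 with the EFM-19 libraries alone and 8 with no filter on low counts. Without single other libraries it called 2 (either MDA-MB-330 DMSO library), 4 (either E2 library) or 7 (either T-47D G-03046274 library). None of the 10 genes was called: ESR1 -0.23 ± 0.05, PGR -0.12 ± 0.10, GREB1 0.04 ± 0.10, TFF1 0.14 ± 0.08, PDZK1 -0.09 ± 0.17, CXCL12 -0.18 ± 0.08, MYC -0.15 ± 0.06, CCND1 -0.02 ± 0.07, AREG -0.20 ± 0.27 and IGFBP4 -0.06 ± 0.05. As a list, fatty acid synthesis genes shifted upward with none of 12 called (1 and 0 alone, median 0.13, adjusted p = 3.50e-10), and so did mitochondrially encoded transcripts (median 0.133, adjusted p = 0.0104, or 0.784 with an estimated correlation). Other lists lost their call with an estimated correlation too. G1/S and DNA replication (median -0.049, adjusted p = 0.00107, or 0.135) and mitosis (-0.045, 1.61e-04, or 0.228) shifted downward. Lysosome genes (0.028, 0.0159, or 0.469) and endothelial markers (0.46, 0.0159, or 0.228) shifted upward. With G-03046274, estrogen-induced genes rose in 18 of 50 cases and fell in 1 (27 and 1 alone, median 0.20, adjusted p = 6.55e-42). PCP2 rose by 2.66 ± 0.17, PGLYRP2 by 2.63 ± 0.14, STC1 by 1.88 ± 0.12, MYB by 1.10 ± 0.10, TFF1 by 0.90 ± 0.07, SLC7A5 by 0.87 ± 0.08, PGR by 0.74 ± 0.09, CA12 by 0.64 ± 0.05 and MYC by 0.36 ± 0.06. IGFBP4 fell by 0.33 ± 0.05, and 3 of 18 estrogen-repressed genes fell (0 and 6 alone, median -0.14, adjusted p = 8.34e-07). IL1R1 was at -0.34 ± 0.05. Of 32 G1/S and DNA replication genes none was called, and the list shifted upward (3 and 0 alone, median 0.11, adjusted p = 2.58e-07). Of 24 cholesterol synthesis genes 2 rose (11 and 0 alone, median 0.14, adjusted p = 2.04e-13). ESR1 (0.18 ± 0.05), GREB1 (0.30 ± 0.10), PDZK1 (0.26 ± 0.15), CXCL12 (0.17 ± 0.07), CCND1 (0.01 ± 0.07) and AREG (0.10 ± 0.25) were not called, and the fall of the tensin gene TNS4 (-0.66 ± 0.11) lost its call without DMSO replicate 2 (adjusted p = 0.0778). Tested directly, GDC-0927 gave lower PCP2 (-2.62 ± 0.17), PGLYRP2 (-2.54 ± 0.14) and STC1 (-1.99 ± 0.12) and higher TNS4 (0.68 ± 0.11), with 19 of 50 estrogen-induced genes lower and 1 higher (1 and 29 alone, median -0.23, adjusted p = 4.59e-41). G-03046274 changed 137 genes (95 higher) and the direct test called 205 (68 higher). With the EFM-19 libraries alone these were 1490 and 1915, with limma-voom 261 and 329 and with no filter on low counts 221 and 350, and DESeq2 gave 212 for the former. With any 1 of the 4 libraries left out the tests gave 59 to 75 and 70 to 86, and a T-47D G-03046274 library 331 and 441 or 445.

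In T-47D GDC-0927 lowered CISH, a suppressor of cytokine signalling, by a log2 fold change of -1.84 ± 0.10, CXCL12 by -1.72 ± 0.08 (8.40 against 27.6 CPM) and PPM1K by -1.21 ± 0.09. Estrogen-induced genes fell in 9 of 50 cases (2 and 12 alone, median -0.06, adjusted p = 6.07e-17) and G1/S and DNA replication genes in 4 of 32 (0 and 21 alone, median -0.18, adjusted p = 2.79e-26). Non-polyadenylated RNAs shifted downward too (median -0.94, adjusted p = 8.90e-06, or 0.0992 with an estimated correlation), and DMSO replicate 1 held 283 CPM of them against 118 in its duplicate, scaled to the library total alone. GREB1 (-0.21 ± 0.09), TFF1 (-0.58 ± 0.18), PDZK1 (0.46 ± 0.22), CCND1 (-0.03 ± 0.07), AREG (-0.16 ± 0.12) and IGFBP4 (-0.09 ± 0.05) were not called. MYC (-0.48 ± 0.08) and PGR (-0.34 ± 0.06) lost their call without DMSO replicate 1 (adjusted p = 0.0813 and 0.161) or GDC-0927 replicate 1 (0.081 and 0.34), and ESR1 (-0.20 ± 0.05) without these or GDC-0927 replicate 2 (0.546, 0.814 and 0.0623). With G-03046274, KRT13 rose by 6.05 ± 0.28 (13.8 against 0.204 CPM), the potassium channel gene KCNK5 by 2.73 ± 0.17, MAN1C1 by 1.78 ± 0.14, PDZK1 by 1.76 ± 0.19 and STC2 by 1.00 ± 0.07, and CISH fell by 2.17 ± 0.11 and IGFBP4 by 1.03 ± 0.05. CXCL12 was at -0.70 ± 0.08, AREG at -0.60 ± 0.13, MYC at -0.32 ± 0.08, PGR at -0.21 ± 0.06 and CCND1 at 0.22 ± 0.07, all called, but AREG not without G-03046274 replicate 2 (adjusted p = 0.0617), MYC not without it (0.0962), PGR not without DMSO replicate 1 (0.0922) and CCND1 not without DMSO replicate 2 (0.497) or G-03046274 replicate 2 (0.04, 0.885). CCND1 was at 0.36 without G-03046274 replicate 1. ESR1 (-0.07 ± 0.05), GREB1 (-0.17 ± 0.09) and TFF1 (0.17 ± 0.17) were not called. Of the estrogen-induced genes 19 of 50 rose and 13 fell (19 and 13 alone, median 0.02, adjusted p = 0.115). The largest falls, RPPH1 (-4.69 ± 1.35), RN7SK (-3.99 ± 1.11) and RMRP (-3.32 ± 0.94), were small RNAs that stood high in DMSO replicate 1, and without it they were at -0.99, -0.74 and -0.60 (adjusted p = 0.764, 0.739 and 0.744); their calls also ended without G-03046274 replicate 2. With the T-47D libraries alone, the calls of MYC, PGR and ESR1 with GDC-0927 and of CXCL12, AREG, MYC, PGR, CCND1 and the 3 small RNAs with G-03046274 ended.

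G-03046274 replicate 2 stood apart from its duplicate in T-47D. Mitochondrially encoded transcripts took 3.33% of its counts against 1.91%, and expression relative to replicate 1 rose with transcript length, by 0.157 log2 per doubling. The other T-47D duplicates differed along length too, with slopes of -0.085 in DMSO and 0.052 in GDC-0927. The correlations with log2 length were 0.49, -0.498 and 0.445 for G-03046274, DMSO and GDC-0927. Fold changes of G-03046274 against DMSO had a slope of 0.129 with all libraries and 0.049 without G-03046274 replicate 2. Beside the counts of T-47D stood 10 of 15 mitochondrially encoded transcripts that rose with G-03046274 (11 and 0 alone, median 0.74, adjusted p = 3.22e-05, or 0.488 with an estimated correlation) and 7 of 18 non-polyadenylated RNAs that fell (0 and 10 alone, median -1.58, adjusted p = 0.00161, or 0.488 with an estimated correlation; median -1.26 with 1 member at its bound). Without replicate 2 the mitochondrial list lost its call (median 0.19, adjusted p = 0.0577). G-03046274 changed 3890 genes (2140 higher), but 505 without replicate 2, 545 without DMSO replicate 2 and 7064 without replicate 1, and 70 with the T-47D libraries alone. GDC-0927 changed 60 genes (14 higher), 22 without GDC-0927 replicate 1, 31 without replicate 2, 32 without DMSO replicate 1, 107 without either G-03046274 library, 91 with no filter on low counts and 3 with the T-47D libraries alone. Tested directly, GDC-0927 gave lower KRT13 (-6.67 ± 0.29), KCNK5 (-2.99 ± 0.17) and STC1 (-2.17 ± 0.12) and higher KRT222 (1.37 ± 0.17) than G-03046274, with 22 of 50 estrogen-induced genes lower and 7 higher (9 and 25 alone, median -0.23, adjusted p = 3.67e-10). Mitochondrially encoded transcripts were lower in 10 of 15 cases in it (0 and 11 alone, median -0.732, adjusted p = 4.72e-06, or 0.339 with an estimated correlation). Without G-03046274 replicate 2 the median of this list in the direct test was -0.152. That test called 2820 genes (1240 higher), but 367 without G-03046274 replicate 2, 479 without GDC-0927 replicate 1, 1854 without GDC-0927 replicate 2, 6731 without G-03046274 replicate 1 and 61 with the T-47D libraries alone.

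**Figure D3:**
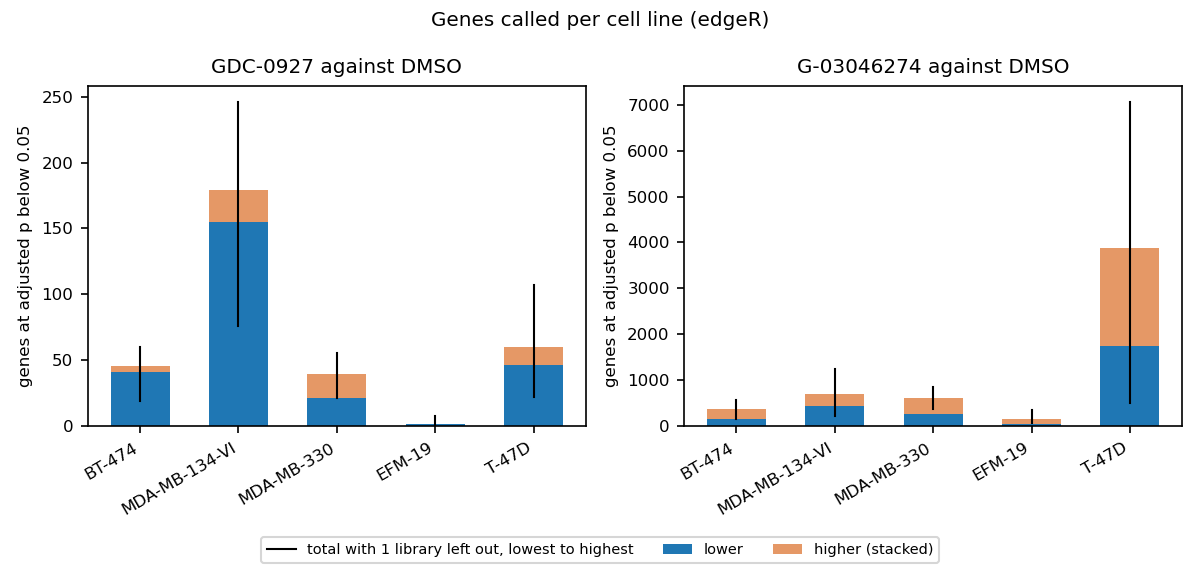
Number of genes called lower and higher (stacked bars) with GDC-0927 and G-03046274 against DMSO in each line; black lines run from the lowest to the highest total with 1 library left out. G-03046274 in T-47D gave 3890 genes, with 505 to 7064 when 1 library was left out.

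Averaged over the 5 lines, GDC-0927 lowered HERC6 by 0.87 ± 0.15 on the log2 scale, with log2 fold changes of -0.86 ± 0.05 for PPM1K, -0.72 ± 0.04 for FGD3 and -0.28 ± 0.02 for ESR1, and raised RRAGD (0.29 ± 0.06), the sterol regulator gene SREBF1 (0.20 ± 0.04) and SCD (0.27 ± 0.02). G1/S and DNA replication genes fell in 17 of 32 cases (0 and 29 alone, median -0.13, adjusted p = 6.86e-52), cholesterol synthesis genes rose in 4 of 24 (5 and 0 alone, median 0.05, adjusted p = 6.42e-09), and estrogen-induced genes fell in 10 and rose in 4 of 50 (7 and 13 alone, median -0.03, adjusted p = 0.0515). Non-polyadenylated RNAs shifted downward (median -0.163, adjusted p = 0.0134, or 0.304 with an estimated correlation). Other called averages lost their call when differences between lines entered the spread (an additive model of line and ligand): STC2 (-0.53 ± 0.03; adjusted p = 0.154), MGP (-0.48 ± 0.05; 0.953), IGFBP4 (0.32 ± 0.02; 1), ANXA9 (0.30 ± 0.03; 0.653) and TFF1 (-0.24 ± 0.05; 1). MYC (-0.24 ± 0.05) lost it without MDA-MB-330 DMSO replicate 1 (adjusted p = 0.0539), AREG (-0.30 ± 0.08) and PGR (-0.39 ± 0.10) with limma-voom (both 0.129) and without any of 17 and 14 single libraries. GREB1 (-0.09 ± 0.04), PDZK1 (-0.18 ± 0.18) and CCND1 (-0.01 ± 0.03) were not called. CXCL12 averaged 13.9 CPM against 18.0 and has no average fold, as a line stood at 0. The test called 42 genes higher and 180 lower, 346 in all without either T-47D G-03046274 library and 78 with the additive model.

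G-03046274 raised PGLYRP2 by 3.69 ± 0.14, SYNPO2L by 2.83 ± 0.16, AMZ1 by 1.40 ± 0.10 and RAPGEFL1 by 1.26 ± 0.05 on average over the 5 lines, and lowered HERC6 (-1.18 ± 0.16), PPM1K (-0.90 ± 0.05), PNMT (-0.61 ± 0.10), GCHFR (-0.53 ± 0.06) and AMIGO2 (-0.82 ± 0.10; -0.41 with the additive model). KRT13 averaged 6.71 CPM against 0.816. Interferon response genes shifted downward as a list (median -0.238, adjusted p = 0.00243, or 0.53 with an estimated correlation). Estrogen-induced genes rose in 22 and fell in 5 of 50 cases (25 and 5 alone, median 0.16, adjusted p = 3.14e-28), G1/S and DNA replication genes fell in 11 of 32 (0 and 19 alone, median -0.08, adjusted p = 4.21e-12), and cholesterol synthesis genes rose in 11 of 24 (17 and 0 alone, median 0.10, adjusted p = 1.99e-17). The G1/S average joins a fall in MDA-MB-330 (median -0.26) and an upward shift in EFM-19. For lists and signatures in the averages, p rests on the spread between duplicates and does not measure whether the lines were alike. The additive model was run for genes only. PDZK1 (1.42 ± 0.19) lost its call without BT-474 G-03046274 replicate 1 (adjusted p = 0.195) and PGR (0.34 ± 0.08) without MDA-MB-134-VI DMSO replicate 2 (0.073), AREG (-0.27 ± 0.07) without EFM-19 DMSO replicate 1 (-0.155, 0.472), EFM-19 G-03046274 replicate 2, or BT-474 DMSO or G-03046274 replicate 2, and TFF1 (0.53 ± 0.04), ESR1 (-0.18 ± 0.02) and MYC (0.21 ± 0.04) lost theirs with the additive model (0.0669, 0.0853 and 0.372). GREB1 (-0.03 ± 0.04), CCND1 (0.02 ± 0.03) and IGFBP4 (0.07 ± 0.02) were not called, and CXCL12 stood at 15.2 against 18.0 CPM. In the direct test, PGLYRP2 (-2.56 ± 0.11), SYNPO2L (-2.01 ± 0.14), AMZ1 (-1.59 ± 0.10) and KCNH1 (-1.51 ± 0.20) were lower with GDC-0927 and AMIGO2 (0.92 ± 0.10) and PNMT (0.56 ± 0.10) higher, with 23 of 50 estrogen-induced genes lower and 4 higher (5 and 27 alone, median -0.19, adjusted p = 8.57e-41). Mitochondrially encoded transcripts shifted downward in it (median -0.109, adjusted p = 0.0346, or 0.855 with an estimated correlation). G-03046274 changed 1005 genes (506 higher; 2131 without T-47D G-03046274 replicate 1), and the direct test called 899 (445 higher; 1577 without that library). AMIGO2 was at 0.47 in that test with the additive model.

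Whether the effect of a ligand differed between the 5 lines was tested for each gene. GDC-0927 had effects that differed in 67 genes, among them IGFBP4, which rose in MDA-MB-330 (1.47 ± 0.05) and BT-474 (0.36 ± 0.05) and stood at -0.07 ± 0.05 in MDA-MB-134-VI (adjusted p of the difference 3.74e-17), TFF1 (0.61 ± 0.06 in MDA-MB-330 and -1.18 ± 0.09 in MDA-MB-134-VI; 8.78e-13) and CXCL12 (8.76e-12). G-03046274 had effects that differed in 2121 genes, among them IGFBP4 (1.56 ± 0.05 in MDA-MB-330 and -1.03 ± 0.05 in T-47D; 8.84e-23) and PDZK1 (1.80e-10). Leaving out either T-47D G-03046274 library gave 106 or 107 genes for GDC-0927, and no filter on low counts 145. With no such filter G-03046274 gave 3854. For G-03046274 the count was 6661 without T-47D replicate 1, 1426 without replicate 2, 1391 without MDA-MB-134-VI G-03046274 replicate 2 and 895 without T-47D DMSO replicate 2.

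The genes that E2 raised against fulvestrant in MDA-MB-134-VI were also followed in the other lines. With GDC-0927, 16 fell and 3 rose in BT-474 (median -0.03, camera adjusted p = 1.32e-05), 22 fell and none rose in T-47D (median -0.08, adjusted p = 1.09e-09), 13 rose and 6 fell in MDA-MB-330 (adjusted p = 0.123), and none was called in EFM-19 (adjusted p = 0.233). With G-03046274, 76 rose and 28 fell in MDA-MB-330 (median 0.07, adjusted p = 1.67e-08, but 0.875 with a signature of no minimum fold), 41 rose and 3 fell in EFM-19 (median 0.08, adjusted p = 4.10e-11), 38 rose and 20 fell in BT-474 (adjusted p = 0.0526) and 72 rose and 55 fell in T-47D (adjusted p = 0.302, with a mean of -0.02 and a test direction upward). With the genes E2 raised against DMSO, GDC-0927 in MDA-MB-330 (adjusted p = 0.0374) and G-03046274 in BT-474 (0.00121) and T-47D (0.0141) passed. Without the 21 non-polyadenylated RNAs the numbers in T-47D were 22 fallen with GDC-0927 (median -0.06, adjusted p = 1.41e-08) and 72 risen and 46 fallen with G-03046274 (adjusted p = 0.128), and BT-474 with G-03046274 passed (adjusted p = 0.0454). On average over the lines 52 fell and 9 rose with GDC-0927 (median -0.08, adjusted p = 9.60e-09) and 87 rose and 26 fell with G-03046274 (median 0.06, adjusted p = 4.10e-07).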

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

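The tests of a wider response of T-47D, of the difference between MDA-MB-330 and EFM-19 and of other splits of the libraries were chosen after the results they measure were seen.

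The effect of GDC-0927 differed between the 5 lines in 67 genes by a test of the difference itself (107 without T-47D G-03046274 replicate 2). Among the genes named in the text this held for IGFBP4 (adjusted p = 3.74e-17), TFF1 (8.78e-13), CXCL12 (8.76e-12), MGP (3.41e-08), STC2 (7.40e-08), ANXA9 (1.64e-07), PDZK1 (1.32e-06), FGD3 (1.40e-06), PPM1K (4.58e-06), ESR1 (2.21e-05), MYC (6.32e-05) and AREG (5.42e-04). The effect of G-03046274 differed in 2121 genes (1426 without that library), among them IGFBP4 (adjusted p = 8.84e-23), PGLYRP2 (1.29e-16), TFF1 (6.09e-12), KRT13 (1.11e-10), PDZK1 (1.80e-10), RAPGEFL1 (3.15e-09), ESR1 (4.67e-09), PPM1K (8.54e-09) and SYNPO2L (8.20e-08). The same test gave CXCL12 5.46e-07, GREB1 5.73e-07, PGR 1.12e-06, AREG 5.86e-06, MYC 1.41e-05, AMZ1 3.09e-05, AMIGO2 6.58e-04 and GCHFR 0.0168, and without T-47D G-03046274 replicate 2 the call of GCHFR ended (0.097).

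Estrogen-induced genes answered GDC-0927 more upward in MDA-MB-330 than in BT-474 (median log2 difference 0.326), MDA-MB-134-VI (0.474) and T-47D (0.366). In MDA-MB-330 6 of the 50 had a group at 0 counts, and with those at their bound the median of 0.14 against DMSO became 0.058. G1/S and DNA replication genes answered G-03046274 more upward in EFM-19 than in BT-474 (0.288) and MDA-MB-330 (0.408). Each difference passed camera with an estimated correlation, the weakest at an adjusted p of 6.72e-08. Only pairs of lines in which the list was called in opposite directions were tested, and p was adjusted over these pairs. The same libraries gave the choice and the test, so passing adds no further support.

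G-03046274 called 3890 genes in T-47D and at most 701 in the other 4 lines in the fit of all libraries. Fitted with the libraries of each line alone, T-47D gave 70 genes, MDA-MB-330 460, BT-474 1233, EFM-19 1490 and MDA-MB-134-VI 1788. Each such fit takes its spread from its own line. The G-03046274 duplicates differed most in T-47D (standard deviation of log2 differences 0.308, at most 0.168 in the other lines). These counts therefore cannot say whether the excess is present. The tests that follow used fits of all lines. With each library's trend with transcript length removed T-47D still gave 3006 against at most 791, which argues against that trend as the whole cause. Of 59 genes called at 2-fold from replicate 1 against DMSO, 93.2% had the same sign in replicate 2 against GDC-0927 (55 genes; 95% Clopper-Pearson interval 83.5% to 98.1%), which argues against a wrong label. With 1 G-03046274 library kept per line and replicate 2 of T-47D left out, T-47D gave 477 genes against 101 to 650 or 127 to 766 in the other lines; the choice of replicate moved their counts by up to 1.78 times, so a wider response of this line cannot be told apart from none. The interval around 93.2% takes genes as independent. They come from the same few libraries, so it does not cover variation that they share. A difference of replicate 2 in RNA quality or culture beyond length may remain and was not tested.

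G1/S and DNA replication genes fell with G-03046274 in MDA-MB-330 (median -0.26) and shifted upward in EFM-19 (0.11). With the trend of fold changes with transcript length and GC content removed the median in MDA-MB-330 was -0.274 (bootstrap 95% interval -0.353 to -0.211), and with 1 of the 4 libraries left out it was -0.264 at its weakest, so neither that bias nor a single library accounts for it. The difference between the lines had an adjusted p of 4.81e-09 with an estimated correlation. A response that differs between the lines is therefore a hypothesis, found and tested on the same data; the density of the cultures was not tested and stays open.

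Cholesterol synthesis genes were lower with fulvestrant than with GDC-0927 in MDA-MB-134-VI (median -0.15). With 1 of the 4 libraries left out the median was -0.126 at its weakest, which argues against a single library. The 339 genes that E2 raised 2-fold against DMSO were also lower with fulvestrant, by a median of -0.059 (bootstrap 95% interval -0.093 to -0.025), an interval that spans 50% of the cholesterol difference, so a weaker blockade of estrogen-responsive genes by GDC-0927 could account for part of it and cannot be told apart from an effect on these genes alone. With the trend with length and GC content removed the median was -0.125 (-0.279 to -0.073), an interval too wide to exclude that such a bias carries part of it.

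For the averages, other splits of the same 20 libraries that part the 4 libraries of each line 2 against 2 were fitted, 33 in all with the real one. In these fits the real split called 325 genes for GDC-0927, 686 for G-03046274 and 619 for the direct test, and the highest other split 30, 293 and 97. In each case 1 of the 33 splits, the real one, reached its count. No smaller share is possible with 33 splits, and the test was chosen after the counts were seen. The other splits mixed the ligands within lines, which puts ligand effects into their spread and lowers their counts. Chance is therefore made less likely but is not excluded.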

How the results depend on the processing

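All tests here were planned except those without T-47D G-03046274 replicate 2 on gene lists and signatures and those of a signature without non-polyadenylated RNAs, which were chosen after the results were seen. No count moved by more than 1.5 times with RLE size factors, and the largest shift of the median of all genes was 0.018 log2. Of 1711 called results for named genes, 1031 kept direction and call in every alternative, 680 lost the call in at least 1 and 9 reversed in at least 1. Of 868 list results an estimated correlation ended 129 and RLE ended 2 and added 7. Without T-47D G-03046274 replicate 2, among list results of T-47D and the averages, 11 ended, 10 were added and 1 reversed. In T-47D with G-03046274 the mitochondrial list ended (0.192, adjusted p = 0.0577) and the G1/S list was added (-0.063, adjusted p = 0.00849), as were those of mitosis (-0.072, 0.00849) and cholesterol synthesis (0.072, 0.0111). With GDC-0927 cholesterol synthesis was added (0.047, 0.0301). In the direct test there estrogen-repressed genes were added (0.076, 0.00206) and p53 targets ended (0.064, 0.267), and in its average NRF2 targets (0.081, 0.0508), p53 targets (0.041, 0.134), immediate-early genes (0.007, 0.154) and BCL2-family genes (0.007, 0.349) ended. With all libraries, an estimated correlation in camera had ended these calls too. Adjusted p in the direct average was 0.0828 for NRF2 targets, 0.136 for p53 targets, 0.32 for immediate-early and 0.0828 for BCL2-family genes. For p53 targets in the T-47D direct test it was 0.231. No paired analysis was possible because the labels pair no libraries. With 2 libraries per group, a lone library was assumed to vary like the other groups. Depth limits genes near 0 counts, for which a fitted fold is no measure of the change.

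Fitting only the libraries of the line compared gave 141, 1233 and 1159 genes in BT-474 (GDC-0927, G-03046274, direct), 33, 1490 and 1915 in EFM-19 and 3, 70 and 61 in T-47D. In MDA-MB-134-VI it gave 1478 (4-OH tamoxifen), 567 (fulvestrant), 688 (GDC-0810), 317 (GDC-0927), 1788 (G-03046274) and 2116 (direct), and for the pairs 3872, 495, 2337 and 493 (4-OH tamoxifen against fulvestrant, GDC-0810, GDC-0927 and G-03046274), 3088, 24 and 3958 (fulvestrant against GDC-0810, GDC-0927 and G-03046274) and 2347 and 1408 (GDC-0810 against GDC-0927 and G-03046274). DESeq2 gave 63 for GDC-0927 in MDA-MB-330, 9 and 212 for GDC-0927 and G-03046274 in EFM-19, 367 for 4-OH tamoxifen against G-03046274 and 21 for fulvestrant against GDC-0927. limma-voom gave 4, 261 and 329 in EFM-19 and 189 for 4-OH tamoxifen against G-03046274. Without a filter on low counts the results were 89 (GDC-0927 in MDA-MB-330), 8, 221 and 350 (EFM-19), 91 (GDC-0927 in T-47D), 365 and 234 (4-OH tamoxifen against GDC-0810 and G-03046274) and 145 and 3854 (differences between lines). The additive model gave 78 for the GDC-0927 average. Counts in BT-474, EFM-19 and MDA-MB-134-VI also rose when a T-47D G-03046274 library was left out. That library enters none of their contrasts and can act on them only through what the fit shares, such as the pooled spread. Other causes were not tested.

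With DESeq2 the balance of raised and lowered genes moved for fulvestrant (61 and 231 to 115 and 235), the direct test in MDA-MB-134-VI (543 and 557 to 760 and 477), G-03046274 in EFM-19 (95 and 42 to 119 and 93) and the direct test there (68 and 137 to 129 and 142).

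Leaving out 1 library gave these ranges. BT-474: 19 to 60, 150 to 569, 130 to 455. MDA-MB-134-VI against DMSO: E2 4557 to 6824, 4-OH tamoxifen 272 to 1192, fulvestrant 96 to 448, GDC-0810 109 to 579, GDC-0927 76 to 246, G-03046274 206 to 1229; direct 475 to 1667. MDA-MB-330: 21 to 55, 358 to 847, 328 to 917. EFM-19: 0 to 7, 59 to 331, 70 to 445. T-47D: 22 to 107, 505 to 7064, 367 to 6731. 4-OH tamoxifen against fulvestrant 1135 to 3397, GDC-0810 95 to 370, GDC-0927 722 to 2037, G-03046274 15 to 380. Fulvestrant against GDC-0810 1111 to 2732, GDC-0927 4 to 20, G-03046274 972 to 3343. GDC-0810 against GDC-0927 759 to 2041, G-03046274 130 to 989. E2 against fulvestrant 6005 to 8031, GDC-0810 2946 to 5121. Averages 165 to 346, 777 to 2131, 760 to 1577; differences between lines 47 to 107 and 895 to 6661. The 0 in EFM-19 came from edgeR, where the full fit had 483 genes at an unadjusted p below 0.05, DESeq2 called 9 and limma-voom 4.

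Signature results that crossed the threshold, as median and adjusted p: genes raised by E2 in BT-474 with G-03046274 0.000 and 0.00858 (estimated correlation), 0.041 and 8.84e-04 (signature against GDC-0810), 0.025 and 0.00121 (signature against DMSO), 0.000 and 0.0454 (no non-polyadenylated RNAs); in MDA-MB-330 with GDC-0927 0.015 and 0.0246 (estimated correlation), 0.001 and 0.0448 (RLE), 0.015 and 0.0374 (signature against DMSO); in T-47D with G-03046274 0.003 and 0.0424 (signature against GDC-0810), 0.011 and 0.0141 (against DMSO); 4-OH tamoxifen against GDC-0810 -0.018 and 0.0103 (estimated correlation), -0.006 and 0.0394 (no non-polyadenylated RNAs). With no minimum fold: 0.000 and 0.875 (MDA-MB-330, G-03046274), 0.010 and 0.783 (MDA-MB-330, direct), 0.002 and 0.896 (T-47D, direct). Genes lowered by E2: BT-474 with G-03046274 -0.047 and 0.0483 (signature against GDC-0810), T-47D with GDC-0927 0.015 and 0.067 (signature against DMSO), T-47D direct 0.039 and 0.0433 (without T-47D G-03046274 replicate 2), and with no minimum fold BT-474 direct 0.018 and 0.0922, 4-OH tamoxifen against G-03046274 -0.010 and 0.175, GDC-0810 against G-03046274 -0.007 and 0.0537. The cause was not tested.

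Without E2 replicate 1 RN7SK reversed to -1.245 (against DMSO), -0.354 (fulvestrant) and -0.542 (GDC-0810), and without E2 replicate 2 it was 4.029, 4.921 and 4.734. HIST1H4C went to -0.509 and 2.853 (against DMSO), RPPH1 to -0.382 and 4.655 (fulvestrant) and -0.631 and 4.406 (GDC-0810), and RMRP to -0.030 and 3.727 (GDC-0810). CDH2 in the direct test of MDA-MB-330 had 16 counts against 0, so its fitted 0.000 without GDC-0927 replicate 1 and 6.915 without replicate 2 are not fold changes. NCL with G-03046274 in T-47D went to -0.003 without replicate 2 and 0.365 without replicate 1. The mitochondrial list in the direct average went to 0.003 without T-47D G-03046274 replicate 2.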

Other observations

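No hypothesis beyond those above was tested, and the values here were chosen after they were seen. With E2 in MDA-MB-134-VI the transcription factor gene SNAI1 rose by 2.67 ± 0.23 and the cadherin gene CDH2 was at -1.04 ± 0.09 on the log2 scale, TFAP2C rose by 2.03 ± 0.05 and NRIP1, a corepressor gene, by 1.23 ± 0.05. Among ATF4 and amino acid response genes 4 of 16 rose and 7 fell with E2 (4 and 7 alone, median -0.22, adjusted p = 0.755).

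With counts scaled to the library total alone, RN7SK stood at 76.3 CPM in T-47D DMSO replicate 1 against 4.12 in its duplicate and RMRP at 31.1 against 2.48. In E2 replicate 1 of MDA-MB-134-VI RMRP stood at 23.4 against 1.73. T-47D G-03046274 replicate 2 held 166 CPM of MALAT1 against 67 in its duplicate. Principal components 1 to 4 of the 38 libraries held 43.0%, 22.9%, 15.7% and 14.6% of the variance.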
